A study of Mus musculus with 7 samples.

How the data were processed

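Small RNA of colorectum from 6 mice was sequenced on an Ion Proton after library preparation with the Ion Total RNA-Seq kit, per the labels' protocols. Reads were aligned by the authors with BWA to mm10, which is GRCm38, per the submitters' processing notes. The authors deposited 1 table of whole-number counts, not normalized, for 1915 mature miRNAs with their hairpins, per the file headers. How reads on opposite strands or matching several hairpins were counted is not given in the sources used here. The table has 6 columns. M2 to M6 carry the name of 1 labelled library each. The column M1 carries the id of a mouse with 2 labelled libraries. It was used as 1 healthy replicate, so the planned comparison of the 2 libraries of M1 with each other was not made. Groups were taken from the labels, and mice are separate animals. All rows named a miRNA, and 1 row had 0 counts in all mice.

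Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter by group (878 miRNAs kept), robust dispersions, glmQLFit with robust=TRUE and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of single miRNAs are edgeR's unless another tool is named. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes. TMM factors were 0.720 for M1, 0.582 for M2, 1.10 for M3, 0.948 for M4, 1.55 for M5 and 1.47 for M6. The common coefficient of biological variation was 0.511. Scaling by total counts alone raised the log2 fold changes by a median of 0.71 relative to TMM, so every direction is relative to the TMM scale.

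In total 21 lists of miRNAs (cell types, tumour biology, families and clusters) were fixed before the data were examined, with the design, the alternatives and the rule for named miRNAs. Each list was counted over all miRNAs and adjusted over the list alone. Lists with at least 3 tested members (19 lists) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma 3.58.1. Camera called 5 lists at the preset correlation, 0 at the estimated correlation, and fry 0. At an unadjusted p under 0.05 the estimated correlation gave 0 lists and fry 5. The estimated correlation within a list reached 0.418 (smooth muscle), so p-values at the preset 0.01 can be too small. Camera p-values below are at the preset correlation unless the estimated one is named. Those without a mouse were taken at the preset correlation only. The rule named every measured arm of miR-15a, miR-15b and miR-16; of the calls with a mean of at least 50 CPM in 1 group, the 10 highest and 10 lowest log2 fold changes; the 5 most abundant miRNAs; and up to 4 abundant members of each list. Other miRNAs in the text were chosen after their values were seen. Shares of reads were compared by exact permutation. Arm usage was tested with limma (trend, robust) on log2 ratios of 5p to 3p counts with 0.5 added, for hairpins with both arms at a mean of 10 counts or more.

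The scripts were tested on simulated data for the CRC against healthy comparison: counts of 878 miRNAs were drawn from the real means, totals and dispersions with 200 changed. Of the 878, 822 passed the filter. edgeR called 12.5% of tested miRNAs changed 2-fold, 64.6% at 4-fold, 88.6% at 8-fold and 100% at 16-fold, with 6 false calls among 127. For the arm test, counts of all entries were drawn with the median dispersion in place of their own. In 280 hairpins simulated so, it called 77.5% of those shifted 8-fold. With the smooth muscle list lowered 8-fold and nothing else changed, camera at the preset correlation called 2 lists: that one and the list of miRNAs lower in colorectal cancer, which shares members with it. The simulated miRNAs were drawn independently, so this does not test the preset correlation. None of the simulations held pairs of similar mice, as the real profiles described below do. Rates in the real data may therefore differ. In simulated data with no change edgeR called 1 miRNA. DESeq2 1.42.0 (Wald test) and limma-voom served as other tools. In the simulation with 200 changed, DESeq2 had 13 false calls among 138 and limma-voom 7 among 122.

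The alternatives were other scalings (RLE, upper quartile, totals alone), no filter, a filter at 50 CPM, the other tools, non-robust fits, leaving out each mouse, other thresholds, the more abundant arm of each hairpin, the top 5 miRNAs and a minimum of 50 counts for arms. After seeing the data 6 more were added: leaving out M3 with M4, adding neighbouring mice (M1 with M2, M3 with M4, M5 with M6) as blocks, thinning each profile to 3206127 reads, removing each profile's GC trend by loess (span 0.75) with and without recomputed TMM factors, and summing entries with identical sequences or 19 or more reverse-complement bases. Hairpin positions come from GENCODE M21 on GRCm38, in which 1146 of 1193 hairpins were found by name; exon means overlap with an annotated exon on the same strand. The plots were drawn with matplotlib 3.10.9.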

Results

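MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were counted by small RNA sequencing in the colorectum of wild-type C57BL/6 female mice. The 3 CRC mice had received azoxymethane (AOM), a colon carcinogen, at 10 mg per kg, and 5 days later 2.5% dextran sodium sulfate (DSS), which injures the colon lining, in the drinking water for 7 days. For these mice the labels also give 14 days of water, stage T1 and day 17. From which event day 17 was counted was not established here. The age given for all mice is 7 weeks. The 3 healthy mice had received saline (0.9%). The healthy mice are M1, M2 and M3 and the CRC mice M4, M5 and M6. The labels list 2 libraries of mouse M1, and the count table holds 1 column of that name. Whether that column is the sum of the 2 libraries or either of them is not given in the sources used here, so the comparisons run on 6 profiles, 1 per mouse. Total miRNA reads were 12416552 in M1, 15280434 in M2, 8222508 in M3, 6601899 in M4, 3565435 in M5 and 3206127 in M6. A count of 0 allows up to 0.196 CPM, the count scaled to the total of the library, in M2 and up to 0.936 CPM in M6, the shallowest profile. These floors cover counting error only.

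Smooth muscle miRNAs made up much of the reads in the healthy profiles M1 and M2, a smaller part in M3 and M4 and the smallest in M5 and M6. In M1 and M2, miR-145a-5p alone took 27.8% and 36.7% of the reads, against 13.1% in M3, 14.9% in M4, 3.40% in M5 and 3.50% in M6. The inflammation-related miR-21a-5p ranged from 7.33% of the reads in M1 to 21.5% in M6. On the TMM scale it differed less, with 101850 CPM in M1 and 146828 CPM in M6. Its log2 fold change between CRC and healthy mice was 0.23 (SE 0.29, adjusted p = 0.675, edgeR). The profiles lay in neighbouring pairs: the correlation of log2 CPM across 410 miRNAs was 0.994 between M1 and M2, 0.972 between M3 and M4 and 0.985 between M5 and M6. Between these pairs it was at most 0.933. These are correlations across miRNAs, which are not independent replicates. The healthy profile M3 was thus closest to a CRC profile, M4. No batch or day of library preparation is given in the labels.

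**Figure D1:**
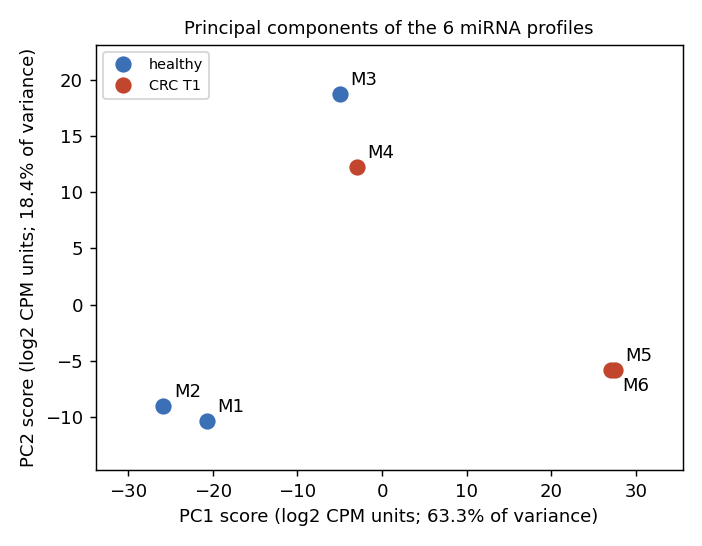
Scores of the 6 profiles on the first principal component (horizontal axis, 63.3% of the variance) and the next component (vertical axis, 18.4%), from log2 CPM of the 878 tested miRNAs; each point is a mouse and the colour gives its group. Healthy M3 and CRC M4 lie next to each other, between M1 with M2 on the left and M5 with M6 on the right.

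The design asks which miRNAs differ between the colorectum of mice with early AOM/DSS tumours and that of healthy mice. No group received only AOM or only DSS. Effects of the carcinogen, of DSS injury and of tumours therefore cannot be told apart, and CRC below names the treated group. In CRC, 20 of 878 tested miRNAs rose and 0 fell in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. The highest log2 fold changes among those named by rule were those of miR-615-3p (5.38, SE 1.07), miR-6937-5p (5.31, SE 0.88) and miR-1224-3p (5.24, SE 0.97). The most abundant was miR-6240, which rose from 175.9 ± 36.8 CPM in healthy mice to 2924 ± 1989 CPM in CRC mice (SD, n = 3 each). The others were miR-6236 (log2 fold change 5.00, SE 0.84), miR-7213-3p (4.87, SE 1.00), miR-6238 (4.57, SE 0.91), miR-320-5p (3.99, SE 0.86), miR-6538 (3.91, SE 0.82) and miR-1247-5p (3.56, SE 0.67). With each profile's GC trend removed, a setting added after seeing the data, none of them was called: miR-6538 had 0.02, miR-6236 2.48 and miR-6240 2.22, and with factors recomputed 0.90, 3.38 and 3.20, of which the value of miR-6538 was not called. Whether entries such as miR-6240, miR-6236 and miR-6238 collect fragments of ribosomal RNA was not tested, so their values are those of the entries.

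Adjusted p-values of the 20 miRNAs in edgeR's test lay between 0.0393 and 0.0464, and their log2 fold changes between 2.69 and 5.38. At an unadjusted p under 0.05 the test held 204 miRNAs, 119 higher and 85 lower; this split was 181 and 16 with total counts as the only scaling and 35 and 191 with the GC trend removed, or 108 and 84 with TMM factors recomputed after that removal. M5 and M6 had far higher values than M4. For miR-615-3p, M4 had 7.99 CPM, M5 257 CPM and M6 198 CPM, against 3.38 to 3.97 CPM in the healthy mice. For miR-6240, M4 had 699 CPM against 3541 CPM in M5 and 4531 CPM in M6. All 20 miRNAs were above every healthy mouse in each CRC mouse, with a median difference of 1.37 log2 units between M4 and M3. Over the 878 miRNAs, 124 were above and 109 below every healthy mouse in each CRC mouse, together 26.5%.

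The number of calls depended on single mice. It was 0 without M1, M5 or M6, 4 without M2, 63 without M3 (29 higher) and 237 without M4 (170 higher). The filter was run again in each of these fits, which tested from 939 (without M6) to 1188 miRNAs (without M4), against 878 with all mice. Without both M3 and M4, a comparison of 2 mice with 2 chosen after seeing the data, edgeR called 576 of 1082 tested miRNAs, 279 higher and 297 lower. With the neighbouring pairs as blocks, also chosen after seeing the data, M3 and M4 alone carry the difference between the groups, 1 mouse against 1, and the spread comes from M1 with M2 and M5 with M6, on the assumption that M3 and M4 vary alike; edgeR then called 27 miRNAs, 13 higher and 14 lower, among them 4 of the 20. The median log2 fold change of the 20 was 1.46 in that fit. On all 6 mice without blocks DESeq2 called 111 (76 higher, 35 lower), and limma-voom called 0, with 216 at an unadjusted p under 0.05.

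**Figure D2:**
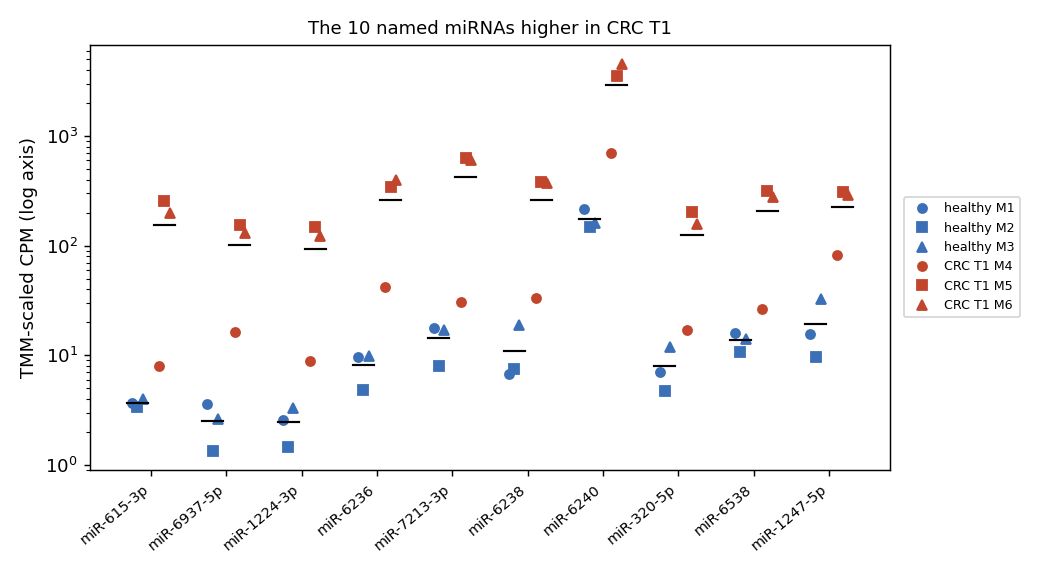
TMM-scaled CPM on a log axis for the 10 named miRNAs higher in CRC; each point is a mouse, with healthy mice in blue and CRC mice in red, and the bar is the group mean (n = 3). M5 and M6 lie far above the healthy mice for each miRNA, and M4 lies between: for miR-6240 it had 699 CPM against 149.2 to 217.8 CPM in the healthy mice.

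The named miRNAs lie at separate places in GRCm38. Mir615 is on chromosome 15 from 103014910 to 103015001 in an intron of Hoxc5. Mir6937 is on chromosome 12 from 28679325 to 28679389 in an intron of Adi1, and Mir1224 on chromosome 16 from 20604452 to 20604536 in an intron of Vwa5b2. Mir7213 is on chromosome 15 from 79998970 to 79999026 in an intron of Pdgfb. Mir1247 overlaps an exon of the noncoding Dio3os on chromosome 12, from 110278048 to 110278129. Mir6240 is on chromosome 5 from 114851948 to 114852064, Mir6236 on chromosome 9 from 110281287 to 110281409 and Mir6238 on chromosome 7 from 53891761 to 53891889, none with a host gene on the same strand. The median GC content of the 20 mature sequences was 60.5%, against 50% over the 878 tested miRNAs.

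The series is about miR-15a and miR-16-1, miRNAs that share a seed and a transcript and are known to restrain cell cycle genes and BCL2. No arm of miR-15a, miR-15b or miR-16 passed the test between CRC and healthy colorectum. miR-15a-5p had 2168 ± 1729 CPM in healthy and 2995 ± 514 CPM in CRC mice (SD, n = 3 each), a log2 fold change of 0.47 (SE 0.54, adjusted p = 0.640, edgeR). Within the healthy group it ran from 928 CPM in M2 to 4144 CPM in M3, a range wider than the difference between the groups. miR-16-5p had 7827 ± 726 CPM in healthy and 5352 ± 1182 CPM in CRC mice (SD, n = 3 each), a log2 fold change of -0.55 (SE 0.34, adjusted p = 0.347, edgeR), and each CRC mouse lay below each healthy mouse. With total counts as the only scaling the miR-16-5p value was 0.11.

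The other arms gave log2 fold changes of 0.42 for miR-15b-5p (SE 0.60), 0.20 for miR-15b-3p (SE 0.40), -0.58 for miR-15a-3p (SE 0.45), -0.38 for miR-16-1-3p (SE 0.48) and -0.23 for miR-16-2-3p (SE 0.43). Of the 15 tested members of the miR-15/16 family list, 0 passed edgeR's test over all miRNAs, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. DESeq2 and limma-voom called neither miR-15a-5p nor miR-16-5p. Without both M3 and M4, miR-15a-5p had a log2 fold change of 1.19 (adjusted p = 0.00057, edgeR) and miR-16-5p of -1.003 (adjusted p = 0.00169, edgeR). In that fit 576 of 1082 tested miRNAs passed, so passing there does not set these miRNAs apart. With neighbouring pairs as blocks, where the difference is M4 minus M3, 1 mouse against 1, miR-15a-5p had -0.77 and was not called. The study may have picked this miRNA pair from these libraries, so its values here are not independent evidence of a direction. In GRCm38, Mir15a lies on chromosome 14 from 61632027 to 61632110, in an intron of the noncoding Dleu2, and Mir16-1 from 61631880 to 61631972, overlapping a Dleu2 exon. Mir15b (69009772 to 69009835) and Mir16-2 (69009902 to 69009996) lie on chromosome 3 in introns of Smc4. Mature miR-16-5p comes from both loci and cannot be assigned to either.

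**Figure D3:**
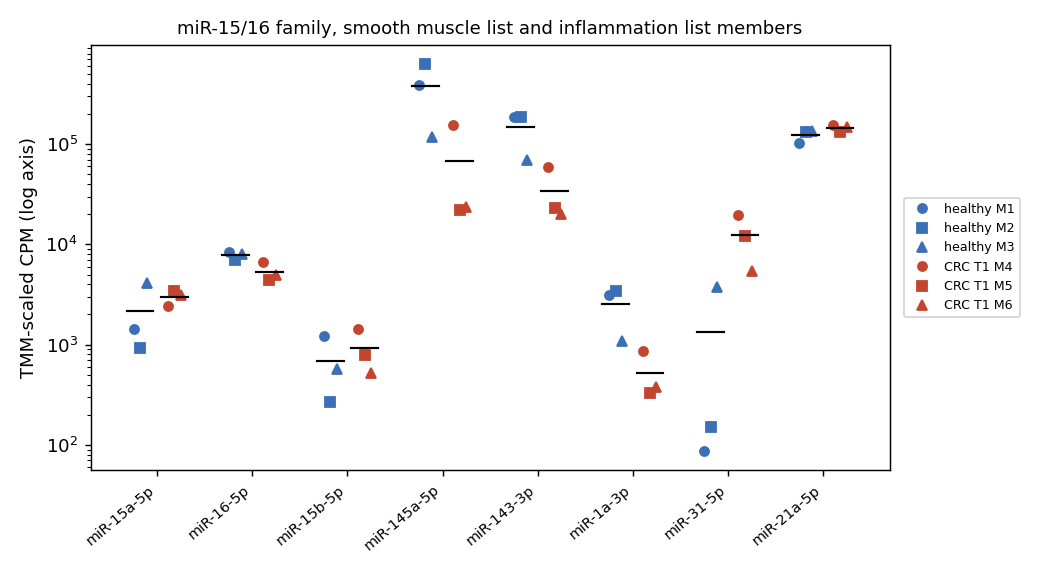
TMM-scaled CPM on a log axis for 3 arms of the miR-15/16 family, 3 members of the smooth muscle list, miR-31-5p and miR-21a-5p; each point is a mouse, with healthy mice in blue and CRC mice in red, and the bar is the group mean (n = 3). None of the 8 passed the test over all miRNAs. Healthy M3 had 4144 CPM of miR-15a-5p, above each CRC mouse, and 3771 CPM of miR-31-5p, below the lowest CRC mouse at 5463 CPM.

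Smooth muscle miRNAs were the list with the lowest log2 fold changes in CRC. Over all miRNAs 0 of its 14 tested members passed edgeR's test, and 13 were at an unadjusted p under 0.05. Adjusted over the list alone, 13 fell. They included the abundant miR-145a-5p (378315 ± 256008 CPM in healthy and 67580 ± 77415 CPM in CRC mice; SD, n = 3 each; log2 fold change -2.48, SE 0.84) and miR-143-3p (148036 ± 68083 against 34268 ± 22072 CPM; SD, n = 3 each; -2.11, SE 0.54). The muscle miRNAs miR-1a-3p (-2.30, SE 0.57) and miR-133a-3p (-1.43, SE 0.54) also fell in that test, while miR-206-3p had 0.18 (SE 1.58). The level of miR-206-3p was not even within the groups: 138 CPM in M3 and 136 CPM in M4. It had 2.46 CPM in M1, 2.25 CPM in M2, 1.99 CPM in M5 and 24.0 CPM in M6. Camera with a preset correlation of 0.01 called the list lower (adjusted p = 2.03e-08); the adjusted p was 0.558 with an estimated correlation and 0.109 in fry. Between the neighbouring profiles, M4 was below M3 for 13 of the 14 members, with -1.36 log2 units for miR-133a-3p and -0.22 for miR-143-3p, and above it for miR-145a-5p (0.41). The 14 entries are not separate measurements. They hold both arms of miR-143, miR-145a and miR-133a, and reverse-complement entries such as miR-1a-3p and miR-1b-5p may share reads. The estimated correlation within the list was 0.418, so both counts of 13 overstate the number of separate changes.

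The list of miRNAs known as lower in colorectal cancer shares its muscle members with that list. Of its 43 tested members 0 passed over all miRNAs and 20 were at an unadjusted p under 0.05; adjusted over the list alone, 4 fell: miR-1a-3p, miR-133a-5p, miR-1a-2-5p and miR-143-3p. Camera called it lower (adjusted p = 1.05e-06). The adjusted p was 0.558 with an estimated correlation and 0.109 in fry. Over all settings the mean log2 fold change of this list lay between -1.55 and -0.16. With neighbouring pairs as blocks camera did not call it lower. Outside muscle, miR-139-5p had a log2 fold change of -1.18 (SE 0.43), miR-30c-5p of -1.003 (SE 0.35) and miR-149-3p of 2.18 (SE 0.72), none past the list's own adjustment. For the list of miRNAs known as higher in colorectal cancer, 29 of 36 tested members had positive values. Of these 36, 0 passed and 2 were at an unadjusted p under 0.05. At the preset correlation the camera adjusted p was 0.0547, or 9.59e-05 without M3 and 0.0268 without M5. With all mice the estimated correlation in this list, 0.291, gave a camera adjusted p of 0.762. Its member miR-31-5p, induced in inflamed and transformed colon epithelium, had 87.2 CPM in M1, 150.4 CPM in M2 and 3771 CPM in M3, against 5463 to 19829 CPM in the CRC mice (log2 fold change 3.22, SE 1.27, adjusted p = 0.169, edgeR).

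The fixed list of the imprinted Dlk1-Dio3 cluster, active in stromal and neural cells, held 73 tested miRNAs, of which 1 rose, miR-323-5p (log2 fold change 3.61, SE 0.74), and 0 fell over all miRNAs; 28 were at an unadjusted p under 0.05. miR-1247-5p in Dio3os, next to Dio3, is not on that list and also rose (3.56, SE 0.67). Of the 73, 67 had negative values. Adjusted over the list alone, miR-323-5p rose and miR-382-3p fell (-2.20, SE 0.49). Its abundant member miR-376a-3p had 360 ± 208 CPM in healthy and 93.6 ± 15.5 CPM in CRC mice (SD, n = 3 each). Camera called the list lower (adjusted p = 2.03e-08; 0.558 with an estimated correlation; fry 0.109). The nerve list held 16 tested miRNAs, with 0 calls over all miRNAs and 5 at an unadjusted p under 0.05. Adjusted over that list alone, miR-124-3p (-2.34, SE 0.60) and miR-7b-5p (-2.07, SE 0.58) fell and miR-219a-1-3p rose (1.92, SE 0.48). Camera gave it an adjusted p of 0.0167, or 0.558 with an estimated correlation, and fry 0.109. With total counts as the only scaling the mean log2 fold change was -0.07 for Dlk1-Dio3 and -0.06 for nerve. With neighbouring pairs as blocks, where the difference is M4 minus M3, camera called neither list lower.

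Intestinal epithelium miRNAs gave no call among 21 tested members, and 3 were at an unadjusted p under 0.05. The enterocyte miRNA miR-192-5p had a log2 fold change of -0.18 (SE 0.44), miR-194-5p of -0.88 (SE 0.43), and miR-200a-3p and miR-200b-3p, which hold cells in an epithelial state, of -0.67 (SE 0.33) and -0.10 (SE 0.32). Camera called the list lower (adjusted p = 0.0241) with a mean log2 fold change of -0.62, which was 0.053 with total counts as the only scaling; the adjusted p was 0.762 with an estimated correlation. Without M5 the camera adjusted p was 0.124. With neighbouring pairs as blocks the mean of this list was 0.18, and camera did not call it lower. The list fibroblast stroma (14 tested, camera adjusted p = 0.127) held miR-214-3p at -0.23 (SE 0.45) and miR-199b-5p at -2.03 (SE 0.64), and 0 of its members passed, with 2 at an unadjusted p under 0.05. Its camera adjusted p was 0.0224 without M1, 0.00608 without M3 and 0.0181 without M4, all at the preset correlation. With all mice the estimated correlation in this list, 0.307, gave a camera adjusted p of 0.762.

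No list of immune or blood cell miRNAs was called. In the myeloid list (9 tested, 1 at an unadjusted p under 0.05), miR-223-3p had 1636 ± 721 CPM in healthy and 1624 ± 656 CPM in CRC mice (SD, n = 3 each). miR-142a-3p had 904 CPM in M1, 536 CPM in M2 and 9953 CPM in M3, against 3181 to 5362 CPM in the CRC mice. The lymphocyte list (14 tested, 2 at an unadjusted p under 0.05) held miR-150-5p at a log2 fold change of -0.34 (SE 0.49) and miR-181a-5p at -0.91 (SE 0.41). In the red blood cell list (7 tested, 2 at an unadjusted p under 0.05), miR-451a had 362 ± 106.3 CPM in healthy and 992 ± 607 CPM in CRC mice (SD, n = 3 each; log2 fold change 1.45, SE 0.53). The inflammation list (23 tested, 2 at an unadjusted p under 0.05) had positive values for 17 members and a camera adjusted p of 0.155, which was 0.000775 without M3. Both are at the preset correlation. With all mice the estimated correlation in this list, 0.229, gave a camera adjusted p of 0.762. Camera, which compares a list with all other miRNAs, gave adjusted p-values of 0.612 for the miR-15/16 family, 0.664 for myeloid cells and for lymphocytes and 0.251 for red blood cells.

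Growth and tumour suppressor families gave no calls either. The miR-17 to miR-92a clusters, which promote proliferation, had positive values for 19 of 21 tested members, with miR-106b-5p at a log2 fold change of 1.02 (SE 0.44) and miR-20a-5p at 0.92 (SE 0.96); the camera adjusted p was 0.220, and 0.0305 without M3. let-7/miR-98 (23 tested) had -0.39 for let-7a-5p (SE 0.40) and a camera adjusted p of 0.292, which was 0.0181 without M4. The p53-induced miR-34a-5p had 0.34 (SE 0.40) and miR-34b-5p -1.02 (SE 0.39). miR-29b-3p had 0.26 (SE 0.33), miR-30a-5p -0.77 (SE 0.33), miR-181b-5p -1.16 (SE 0.45), miR-126a-3p of the endothelium -0.19 (SE 0.34) and the hypoxia miRNA miR-210-3p 0.06 (SE 0.37). At an unadjusted p under 0.05 edgeR held 1 member of the miR-17 to miR-92a list, 1 of the p53 list, 3 of the miR-30 list, 1 of the miR-181 list and 0 of the let-7, miR-29, endothelium and hypoxia lists. Camera's adjusted p was 0.664 for each of the p53, miR-29, miR-30, miR-181 and endothelium lists. These camera values are at the preset correlation. With all mice the estimated correlation gave a camera adjusted p of 0.762 for the miR-17 to miR-92a list and for let-7/miR-98. Pancreas miRNAs had 155 reads in all 6 mice together and were not tested.

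The part of the reads taken by the most abundant miRNAs was compared by permutation, where 3 mice against 3 allow no p below 0.1 and no difference can pass at 0.05. The top 10 held 65.0% ± 7.84 of reads in healthy and 55.0% ± 3.11 in CRC mice (SD, n = 3 each; exact two-sided permutation p = 0.2). miR-143-3p had 10.7% ± 2.87 of reads in healthy and 4.06% ± 1.42 in CRC mice and miR-192-5p had 3.62% ± 0.42 against 5.38% ± 1.10 (SD, n = 3 each), both with an exact two-sided permutation p of 0.1. Shares are parts of a whole, so a fall in an abundant miRNA raises the shares of others. On the TMM scale the direction of miR-192-5p was the opposite, with a log2 fold change of -0.18 (SE 0.44). miR-145a-5p, miR-21a-5p and miR-29b-3p each had an exact permutation p of 0.2, and all 5 an adjusted p of 0.2.

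The balance of the arms of a hairpin was compared in 236 hairpins. limma called 0 of them, and 29 were at an unadjusted p under 0.05. The smallest adjusted p in limma was 0.0664, for miR-185, whose log2 ratio of 5p to 3p counts differed by -2.94 (SE 0.50) between CRC and healthy mice. The 5p to 3p ratio of miR-146a had a difference of -2.48 (SE 0.71), that of miR-222 of 1.88 (SE 0.62) and that of miR-150 of -1.74 (SE 0.60). Among hairpins of the 20 called miRNAs, the differences were 5.48 for miR-323 (SE 1.17), 4.54 for miR-320 (SE 1.15), -5.89 for miR-1224 (SE 1.57) and -1.77 for miR-615 (SE 0.53), each toward the called arm and none past the threshold in limma. Those hairpins were chosen because 1 arm was called in the same counts, so a shift toward that arm follows largely from the choice. Without M4, 9 hairpins were called.

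Some entries are reverse complements of each other and had nearly equal counts. miR-24-3p and miR-3074-5p, which match 20 bases of each other's reverse complement, had 456688 and 458445 reads over the 6 mice, and miR-142a-3p and miR-142b had 171634 and 175109. Likewise miR-126a-5p and miR-126b-3p had 75445 and 75490 reads. miR-1a-3p, from 2 hairpins, had 77640 reads and miR-1b-5p, from 1 hairpin, 38841. In contrast, miR-126a-3p and miR-126b-5p, which match over 19 bases, had 446275 and 5850. Whether such entries share reads is not settled here, so the values of miR-142a-3p and miR-1a-3p above are uncertain. The same holds for counts of list members that include such entries.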

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

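The count of calls depended on the tool, the filter and single mice, and the 6 settings named last were chosen after seeing the data. Against 20 calls, all higher, the counts in edgeR were 28 (26 higher, 2 lower) with RLE factors, 20 with upper quartile factors or a non-robust fit, 43 (42 higher, 1 lower) with total counts only, 64 (52 higher, 12 lower) with no filter and 0 with a filter at 50 CPM, where 322 miRNAs were tested and 76 were at an unadjusted p under 0.05. DESeq2 called 111 (76 higher, 35 lower) and limma-voom 0 (216 at an unadjusted p under 0.05). A threshold of 0.1 gave 80 (64 higher, 16 lower), and a fold change of at least 2 left 20. Leaving out each mouse gave from 0 to 237 calls, from 0 to 170 higher and from 0 to 67 lower. The filter was run again in each fit. It kept 939 to 1188 miRNAs with a mouse left out, 1082 without both M3 and M4, 847 with entries summed and 689 after thinning. With no filter 1914 miRNAs were tested, against 878 in the main fit. The counts were 576 (279 higher, 297 lower) without both M3 and M4, 47 (42 higher, 5 lower) with identical or reverse-complement entries summed, 0 after thinning (152 at an unadjusted p under 0.05), 0 after removing GC trends (226; 35 higher, 191 lower), 15 (14 higher, 1 lower) with TMM factors recomputed after it and 27 (13 higher, 14 lower) with neighbouring pairs as a replicate block. Of the 20 miRNAs, DESeq2 called all 20, the RLE fit 20, the fit with recomputed factors 13, the fit without M3 8, the fit without M2 4 and the block 4.

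miR-16-5p had a log2 fold change of 0.11 with total counts only (adjusted p = 0.864, edgeR). Without both M3 and M4, miR-15a-5p had 1.19 and miR-16-5p -1.003, both past the threshold in edgeR, as were 576 of the 1082 miRNAs tested in that fit. Adjusted p-values of miR-15a-5p ranged from 0.00057 to 0.920 over all settings and those of miR-16-5p from 0.00169 to 0.864. The number of lists called by camera was 5, from 5 to 9 when a mouse was left out and 8 without both M3 and M4; the block gave 1 and other settings 4 to 7. With the block, miR-15a-5p had -0.77, miR-20a-5p -1.59, miR-142a-3p -1.65 and miR-142b -1.63, the last 3 past the threshold in edgeR, and the list intestinal epithelium had a mean of 0.18. The mean of the epithelium list was 0.053 with total counts only. miR-434-3p had 1.248 without both M3 and M4, against -0.11 with all mice. Arm usage had 0 to 9 calls when a mouse was left out, 53 without both M3 and M4 and 0 at a minimum of 50 counts (20 at an unadjusted p under 0.05). The cause of these changes was not tested. Of 1575 values of single named miRNAs under other settings 164 had the opposite sign, 0 of them for the 10 named calls. Those calls were chosen for high fold changes in the same counts, so this 0 follows largely from the choice. Of 341 list values 41 had the opposite sign. The planned fits with library M1a alone, M1b alone or both as separate samples were not run, since the table holds 1 column for that mouse. The groups share no animals, and the labels give no pairs: the block rests on neighbouring numbers and similar profiles, and its difference between groups is M4 minus M3, 1 mouse against 1, with the spread taken from the other pairs.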

Other observations

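Outside the fixed lists, miR-490-3p had 163 ± 92.7 CPM in healthy and 23.8 ± 11.9 CPM in CRC mice (SD, n = 3 each), a log2 fold change of -2.77 (SE 0.63, adjusted p = 0.0518, edgeR), lower in 3 of 3 CRC mice. Of the 20 called miRNAs, 16 carry a number of 1000 or above, as do 287 of the 878 tested (two-sided Fisher's exact test across miRNAs, which are not independent, p = 1.52e-05). Together the 20 took 0.0256% of reads in M1, 0.0141% in M2, 0.0367% in M3, 0.103% in M4, 1.07% in M5 and 1.14% in M6. These values and the tests of depth, GC content, partner arms, reverse-complement entries, M3 with M4, blocks, and grouping for calls and lists were chosen after the result was seen; for depth, GC content and partner arms the bounds on the median were set before those tests were run.

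The 20 miRNAs called higher had a median log2 fold change of 4.02 with a median SE of 0.79. A difference in depth between the groups stays open. With each profile thinned to 3206127 reads the median of the 18 still tested was 4.26 (lower quartile 3.58, median SE 0.87). No adjusted p passed (smallest 0.0524, edgeR). Random thinning changes only the number of reads and keeps each profile's proportions, so the median could hardly fall. Each CRC profile was shallower than each healthy profile, so depth and group cannot be told apart. GC content may account for part of the pattern: removing each profile's trend gave a median of 2.71 (lower quartile 1.69, lowest -0.28, 18 of 20 above 0, median SE 0.70) and 0 calls, while the median of all tested miRNAs moved to -0.73. The bound of 2 was first applied to the median alone, under which GC content would have been argued against; the demand that the lower quartile exceed it too was set after the value was seen. With factors recomputed the median was 3.60 (lower quartile 2.53, lowest 0.49, 20 of 20 above 0) and 13 of the 20 were called. That quartile lies above 2, so the reading of the GC test depends on the factors. More output of the whole hairpin stays open, since only 4 partner arms were tested, with a median of -1.10: the partner of miR-615-3p had 3.52 (SE 0.98) and those of miR-323-5p, miR-320-5p and miR-1224-3p -1.90, -1.09 and -1.12. Of the 10 splits of the 6 mice, 1, the real split, gave 20 calls, and the highest other gave 0; 10 splits are too few for a share under 0.05.

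Healthy M3 and CRC M4 had closer profiles than either had to its own group. Handling of the mice in pairs of neighbouring numbers is a candidate explanation: the lowest correlation within the 3 pairs exceeded the highest between pairs by 0.0386, but M1 with M2 and M5 with M6 each hold a single group, so pair and group cannot be told apart there. With pairs as blocks edgeR called 27 miRNAs, 4 of them among the 20. Swapped labels of M3 and M4 also stay open: of 472 miRNAs more than 1 log2 unit apart between M1/M2 and M5/M6, 49.2% had the same sign in M4 minus M3. With those labels swapped, edgeR called 0 miRNAs against 20, and 255 against 204 at an unadjusted p under 0.05. A difference between these mice in disease stage or in the tissue sampled was not tested.

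Many entries that are reverse complements of each other had nearly equal counts. Counting of reads on both strands is a candidate explanation that stays open. The pairs compared had 100 or more reads each and equal numbers of hairpins. In the 17 with 19 or more shared bases the median absolute log2 ratio of counts was 0.094. In the 26 with 15 or more it was 0.149, but 9 were more than 2 times apart (upper quartile 1.66). Some of the 9 are arms of the same hairpin, such as miR-299a-5p and miR-299a-3p. Others pair different copies, such as miR-24-2-5p with miR-3074-1-3p, or differently named hairpins, such as miR-151-5p with miR-708-3p. Arms of a hairpin lie at different places, and so may copies and separate hairpins. Counting on both strands need not make such entries equal. However, miR-126a-3p and miR-126b-5p, from overlapping hairpins on opposite strands, were also among the 9. Over 1000 random pairs of miRNAs the median was 2.88. True transcription of both strands at equal levels was not tested.

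For arm usage the real split gave 0 hairpins, so all 10 of the 10 splits reach that count by construction and the comparison decides nothing; the highest other gave 2. For the lists called by camera, 3 of the 10 splits gave as many as the real 5, and the highest other, with M3 and M4 exchanged, gave 7; 10 splits are too few for a share under 0.05.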
